A study of Mus musculus with 8 samples.

How the data were processed

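Dendritic cells were grown from bone marrow of C57BL/6 mice in medium with GM-CSF (20 ng/ml) plus IL-4 (10 ng/ml), which was partly renewed on days 3 and 6, per the labels' protocols. The cells had the genotype RelB-DBDB or IFNAR;RelB-DBDB and were left as controls (labelled 1 h) or given 0.1 µM CpG oligonucleotide for 1, 3 or 8 h. Stranded mRNA libraries were made from 1 µg of RNA with a KAPA kit and sequenced as single-end reads of 50 bp on an Illumina HiSeq instrument, per the labels' protocols. Adapters were trimmed with cutadapt, edgeR was used and the genome build was mm10, per the submitters' processing notes. The aligner, the counter, the annotation and the versions of the authors' tools are not given in the sources used here, and neither is whether counting used strand, so overlapping and antisense genes could not be separated.

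The signal values deposited by the authors are CPM plus 1 (CPM being read counts scaled to a common library total, with no further factor), which was found by testing the file. In each of the 8 columns the lowest value is 1, the values minus 1 sum to the same total, and 100% of the values minus 1 are whole multiples of 1 read within a tolerance of 0.01 read. From this step the reads of each library were worked back, from 3711818 reads (IFNAR;RelB-DBDB, 8 h) to 37221530 reads (RelB-DBDB, 8 h), and a count of 0 allows up to 3 reads, which is 0.0806 to 0.808 CPM. The table has 27178 rows. Of these, 2161 have no gene name and hold 0.0737% to 0.131% of the reads of each library. They counted toward library totals and were otherwise left out. Another 11 names occur on more than 1 row. Their rows were tested separately and are not named. Of 25006 names, 23470 matched 1 gene of GENCODE release M21 on mm10, from which coordinates were taken, and Yam1 matched none. The table also has 16 columns of other samples, which were not used in any step.

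The planned design assumed counts, and stated a limma test for a file of normalized values, which was used. Genes with at least 1 CPM in at least 2 of the 8 libraries were tested (12297 genes). log2(CPM + 1) was fitted with limma 3.58.1 (eBayes with a trend) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A log2 change on this scale understates the change of low genes. The changes at 1, 3 and 8 h against control and the genotype difference (IFNAR;RelB-DBDB minus RelB-DBDB) came from an additive model of genotype and condition on all 8 libraries, with 3 residual degrees of freedom. Since each genotype and condition has 1 library, the spread comes from genotype by condition differences and culture variation together, and a lone library is taken to vary like the others. The late-phase test set the genotype difference at 3 and 8 h against that in control and at 1 h, with 2 residual degrees of freedom. Differences between 2 single libraries are given as values. Their ratios have exact 95% intervals of a comparison of 2 Poisson counts, and intervals and floors cover counting error only.

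Gene lists were tested by camera in limma with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists within a comparison, then with an estimated correlation and with fry. The estimated correlation rests on the residual degrees of freedom alone (3, or 2 in the late phase). That setting has little power, so a list that misses the threshold there is not shown to be unchanged. There were 31 lists, 21 of gene programmes and 10 of cell type markers. The programmes were antiviral interferon-stimulated genes, guanylate-binding and immunity-related GTPases, type I and III interferons, inflammatory cytokines and enzymes, chemokines, NF-κB subunits and feedback regulators, immediate-early genes, the endosomal Toll-like receptor pathway, dendritic cell maturation, MHC class II and class I presentation, anti-inflammatory regulators, sterol synthesis, glycolysis, cell cycle, stress response, IL-4-responsive genes, oxidative phosphorylation, sex-linked genes, neighbours of Ifnar1, and mitochondrially encoded and nuclear-retained RNAs. The marker sets were for dendritic cells, macrophages and monocytes, neutrophils, mast cells and basophils, eosinophils, plasmacytoid dendritic cells, B cells, T and NK cells, erythroid cells and stromal cells. Lists with fewer than 5 tested members were not tested. In single libraries a list's median was placed among 10000 random lists of the same size drawn within 20 bins of mean expression, with intervals from 1000 bootstrap draws over members. Both take genes as independent, so a list whose members move together falls outside random lists more easily. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

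Lists, comparisons and the rule for naming genes were set before the data were examined. Ifnar1, Ifnar2, Relb, Tlr9, Ifnb1, Tnf, Il6, Il12b, Il1b, Cxcl10, Isg15, Irf7, Nfkbia, Actb and Gapdh were named throughout. For each CpG time the 8 largest increases and 5 largest decreases among called genes of the same sign in both genotypes with a mean log2 of at least 3 were named. For the genotype difference these were the 10 largest each way of the same sign in all 4 conditions with a mean log2 of at least 1. For the late phase, with no gene called, they were the 5 largest each way with a mean log2 of at least 3. From each list up to 4 called members were named, or the 2 largest where none was called, and per condition the 5 largest genotype differences each way among genes with at least 50 reads in 1 of the 2 libraries. Genes without a symbol and predicted genes were left out. Names beyond this rule, such as further called members of a list, Xist, and Ifng outside 3 h, were chosen after their values were seen. Some list members that the rule names are given only within their list's count.

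The procedure was tested on simulated data in which 200 of the 12297 genes were changed singly and a further set was raised 2-fold as a list. Recovery was counted over the 200, and calls in the further set did not count as false. The simulated late-phase change was equal at 3 and 8 h, so its recovery does not hold for genes that changed unequally. Noise was drawn gene by gene around the fitted model, with no deviation shared between genes or by a whole library. The rates of recovery and of false calls therefore need not hold for the real libraries. At a 4-fold change the procedure recovered 92% of the changed genes for 1 h, 3 h, 8 h and the genotype difference and 85% for the late phase. At a 2-fold change it recovered 50%, 45%, 43%, 67% and 28%, and 8.19%, 5.13%, 8.24%, 7.96% and 6.98% of the calls were false. Alternatives tried were median-ratio and TMM factors, no filter, a filter of 50 reads in 2 libraries, pseudocounts of 0.1 and 5, limma-voom on the worked-back reads, a test against a fold of 1.5, models without the genotype or condition term, other late phases, and each library or pair left out in turn.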

Results

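Dendritic cells were grown from the bone marrow of mice of 2 genotypes and stimulated with CpG, an unmethylated DNA oligonucleotide that activates the endosomal receptor TLR9, and their mRNA was sequenced. One genotype was RelB-DBDB, named for the NF-κB subunit RelB. The other was IFNAR;RelB-DBDB, which per the series description also lacks the type I interferon receptor IFNAR. Each genotype had 1 library from control cells, labelled 1 h, and 1 library each after 1, 3 and 8 h of 0.1 µM CpG, which makes 8 libraries. No control was labelled 3 or 8 h, so changes at those times hold any effect of longer culture together with that of CpG. The series is concerned with how RelB limits inflammatory genes driven by NF-κB. The RelB-DBDB libraries held 10514734 reads (control), 6159951 (1 h), 8773352 (3 h) and 37221530 (8 h). The IFNAR;RelB-DBDB libraries held 11977778 reads (control), 11779181 (1 h), 5492066 (3 h) and 3711818 (8 h). With 1 library per genotype and condition, and no label that names separate cultures or animals, no p-value given here measures the spread between repeated cultures. Those of limma rest on the spread between these libraries, partly shared over all genes. Those of camera with the preset correlation set list members against other genes within these libraries, so small ones do not stand for replicates. Values are CPM (reads scaled to a common library total) of single libraries, without replicates, and log2 changes are of CPM + 1.

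Ifnar1, which encodes a chain of the type I interferon receptor (chromosome 16, 91485238 to 91507441 of mm10), was read in every library. In RelB-DBDB it stood at 127 CPM in control cells, 122.9 CPM at 1 h, 102 CPM at 3 h and 125 CPM at 8 h. In IFNAR;RelB-DBDB it stood at 86.3, 102, 56.1 and 68.2 CPM, lower in 4 of 4 conditions. The log2 difference was -0.63 ± 0.129 (SE, adjusted p = 0.034 by limma). That call ended without either control library, either 1 h library or either 3 h library, with adjusted p up to 0.189 and down to 0.00946 over the 8 libraries left out in turn. Ifnar2, which encodes the partner chain, showed a log2 difference of -0.04 (adjusted p = 0.861). None of the 25 tested neighbours of Ifnar1 on chromosome 16 differed between genotypes, over all genes or adjusted over the list alone. Relb, which both genotype names carry, stood at 115, 102, 197 and 92.5 CPM in RelB-DBDB and at 121, 116, 206 and 197 CPM in IFNAR;RelB-DBDB (control, 1, 3 and 8 h), with a log2 genotype difference of 0.35 (adjusted p = 0.302). Values per gene do not show whether part of a transcript is missing.

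The first question was which genes responded to CpG within 1 h in both genotypes. Tnf, which encodes the inflammatory cytokine TNF, rose most (34.1-fold on the CPM + 1 scale). With it rose Il1b, the chemokine gene Cxcl2, the NF-κB regulators Nfkbiz, Nfkbia and Tnfaip3, the cytokine-signal inhibitor Socs3 and the immediate-early factor Egr1. These 8 genes were all that passed the threshold among 12297 tested, each higher in both genotypes. Tnf (chromosome 17, 35199381 to 35202007) went from 8.08 to 298 CPM in RelB-DBDB and from 10.6 to 408 CPM in IFNAR;RelB-DBDB, a log2 change of 5.09 ± 0.143 (SE, adjusted p = 3.57e-05). Nfkbiz changed by 4.36 ± 0.256 (adjusted p = 0.00211), from 6.66 to 111 CPM and from 5.34 to 182 CPM. Socs3 changed by 4.03 ± 0.236 (adjusted p = 0.00211) and Egr1 by 3.74 ± 0.243 (adjusted p = 0.00231). Egr1 was back at 6.38 and 11.1 CPM by 3 h. Cxcl2 went from 6.85 to 68.2 CPM in RelB-DBDB and from 1.59 to 39.7 CPM in IFNAR;RelB-DBDB, a log2 change of 3.56 (adjusted p = 0.00231), with the caution that short reads can be shared between Cxcl2 and its near copy Cxcl3. Il1b changed by 3.04 (adjusted p = 0.00231), Tnfaip3 by 1.88 and Nfkbia by 1.43 (adjusted p = 0.0328 for both). Without the IFNAR;RelB-DBDB 1 h library the adjusted p of Egr1 was 0.0619. The Nfkbia call ended in 6 of the 8 fits with 1 library left out (adjusted p 0.000459 to 0.637) and the Tnfaip3 call in 5 of them (adjusted p 0.00201 to 0.55). Tnfaip3 also missed the threshold with median-ratio (adjusted p = 0.051) and TMM factors (0.0512). With no filter Nfkbia and Tnfaip3 missed it (0.188 for both), and against a fold of 1.5 as well (0.286 and 0.187). Without the genotype term Il1b (0.84), Cxcl2 (0.597), Nfkbia (0.0686) and Tnfaip3 (0.0687) did. Il6 (log2 2.62, adjusted p = 0.116) and Il12b (2.55, adjusted p = 0.0963) did not pass with all libraries. Both passed without the RelB-DBDB 1 h library (0.0431 and 0.0333) and without the 8 h library of RelB-DBDB (0.00481 and 0.00533) or of IFNAR;RelB-DBDB (0.00627 and 0.00667). Relb stood at -0.12, Tlr9 at -0.10, Ifnar1 at 0.10, Isg15 at -0.04, Irf7 at -0.10, Cxcl10 at 1.77, Actb at -0.02 and Gapdh at 0.03, with no call. The count of 8 became 35 without the RelB-DBDB 8 h library, 34 without the IFNAR;RelB-DBDB 8 h library and 5 without the IFNAR;RelB-DBDB 1 h library.

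Among gene lists fixed before the data were examined, 7 moved upward at 1 h by camera. Their median log2 changes were 0.754 for inflammatory, 0.557 for immediate-early, 0.313 for chemokine and 0.164 for NF-κB regulator genes. For maturation genes, anti-inflammatory regulators and the Toll-like receptor pathway they were 0.124, 0.0582 and 0.0178, so the typical member of these hardly moved. The 23 inflammatory cytokine and enzyme genes rose as a list (adjusted p = 2.48e-44), with 2 called and 11 higher when adjusted over the list alone, and adjusted p = 0.0646 with an estimated correlation. The 26 immediate-early genes, which code for quickly induced transcription factors, had 1 called and 14 adjusted over the list alone (adjusted p = 5.02e-36, or 0.0996 with an estimated correlation). The 23 NF-κB subunits and feedback regulators had 3 called and 5 adjusted over the list alone (adjusted p = 3.71e-18, or 0.0646 with an estimated correlation). The 17 chemokines had 1 called and 4 adjusted over the list alone (adjusted p = 1.41e-14, or 0.0646 with an estimated correlation). Dendritic cell maturation genes (adjusted p = 3.22e-07, or 0.371 with an estimated correlation), anti-inflammatory regulators (0.00087, or 0.219) and the endosomal Toll-like receptor pathway (0.0028, or 0.251) followed, each with 1 member adjusted over the list alone. The Toll-like receptor list lost its call without the RelB-DBDB control library (adjusted p = 0.241) or the IFNAR;RelB-DBDB 1 h library (adjusted p = 0.46). By fry the immediate-early (adjusted p = 0.0854), maturation, Toll-like receptor (0.785 for both) and anti-inflammatory lists (0.235) did not pass at 1 h. Without the RelB-DBDB 1 h library 12 lists passed, and without that of IFNAR;RelB-DBDB 11.

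By 3 h many more genes had changed. Il1b, which encodes IL-1β, rose 91.9-fold, and Il1a, Il12b, Il6, Cxcl2, Cxcl3, Tnf, Nfkbiz and Ptgs2, the inducible cyclooxygenase, rose with it. The transcription factor genes Klf4, Klf2 and Lyl1 fell. Limma called 924 genes, 448 higher and 476 lower, all 924 with the same sign in both genotypes, and 325 of the higher and 289 of the lower genes changed at least 2-fold. The shared sign follows largely from the model at each time. Its spread comes from disagreement between the genotypes, so genes of opposite sign can hardly be called. The median of all genes shifted by -0.16 on the log2 scale at 3 h, -0.23 at 8 h, -0.01 at 1 h and 0.11 between genotypes. With median-ratio factors, which remove this shift, 3 h gave 961 genes, 596 higher and 365 lower, and with TMM factors 573 higher and 388 lower. Il1b (chromosome 2, 129364570 to 129371139) reached 428 CPM in RelB-DBDB and 843 CPM in IFNAR;RelB-DBDB, a log2 change of 6.52 ± 0.194 (SE, adjusted p = 2.71e-05). Cxcl2 changed by 5.93 (adjusted p = 0.00013), Il12b by 5.79 (adjusted p = 0.00041), Tnf by 5.36 (adjusted p = 2.47e-05), Nfkbiz by 5.36 (adjusted p = 0.000249) and Cxcl3 by 4.91 (adjusted p = 0.000338). Ptgs2 changed by 5.90 ± 0.503, Il1a by 5.74 ± 0.504 (adjusted p = 0.00216 for both) and Il6 by 4.54 ± 0.365 (adjusted p = 0.00195). Cd40, a costimulatory receptor gene, rose by 3.13 on the log2 scale. Klf4 (chromosome 4, 55527143 to 55532466) went from 82.8 to 7.87 CPM and from 88.6 to 7.10 CPM, a log2 change of -3.35 ± 0.175 (adjusted p = 0.000338). Tbc1d2 (-2.50), Tmem86a (-2.48), Pou4f1 (-2.43) and Lyl1 (-2.40) followed it down. Cxcl10, a chemokine gene induced by interferons, stood at 4.13 ± 0.955 (adjusted p = 0.0461), from 1.33 to 72.5 CPM in RelB-DBDB and from 5.59 to 63.4 CPM in IFNAR;RelB-DBDB. Ifnb1, which encodes interferon β, stood at 1.00 (adjusted p = 0.0435) on 8 and 6 reads, and with a pseudocount of 5 it missed the threshold (adjusted p = 0.0981). Isg15 (1.76), Irf7 (0.62), Tlr9 (-0.53), Ifnar1 (-0.46), Actb (0.54) and Gapdh (-0.13, above 0 with either other scaling) had no call. With 1 library left out Irf7 lay between -0.766 and 2.00 and Isg15 between 0.831 and 2.68. Relb at 0.77 (adjusted p = 0.123) passed with median-ratio factors (0.93, adjusted p = 0.0378).

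Single libraries weighed heavily on the 3 h count. It was 12 without the RelB-DBDB 3 h library and 48 without the IFNAR;RelB-DBDB 3 h library. Without the RelB-DBDB control it was 90, without the IFNAR;RelB-DBDB control 125, and without the RelB-DBDB or the IFNAR;RelB-DBDB 1 h library 507 or 503. Without the RelB-DBDB 8 h library it rose to 4313, and without the IFNAR;RelB-DBDB 8 h library to 4295. Cxcl10 (adjusted p 0.000179 to 0.36) and Ifnb1 (0.017 to 0.311) each lost the call in 6 of these 8 fits, all but those without an 8 h library. The Cxcl10 call at 3 h also ended with median-ratio factors (adjusted p = 0.0543), with TMM factors (0.0546), with no filter (0.11), with the filter of 50 reads (0.0511), by limma-voom (0.0705) and against a fold of 1.5 (0.175). Against that fold Ifnb1 missed the threshold too (0.881). Without the genotype term Cxcl10 (0.0698), Ifnb1 (0.11), Cxcl3 (0.0921) and Pou4f1 (0.262) did. Without the RelB-DBDB or the IFNAR;RelB-DBDB 8 h library, Ifnar1 (adjusted p = 0.025 or 0.0262), Relb (0.000203 or 0.000263), Tlr9 (0.003 or 0.00302), Isg15 (0.0238 or 0.025) and Actb (0.00168 or 0.00171) passed at 3 h, and Actb also passed by limma-voom (0.0246). Without the RelB-DBDB 3 h library, Il6 (adjusted p = 0.0828), Ptgs2 (0.0828), Il1a (0.0821), Nfkbia (0.0866), Tbc1d2 (0.0921), Tmem86a (0.0651), Pou4f1 (0.0628) and Lyl1 (0.135) missed the threshold with the same sign as before. Without the IFNAR;RelB-DBDB 3 h library, Il1a (0.0632), Nfkbia (0.0553), Tbc1d2 (0.0771), Pou4f1 (0.0616) and Lyl1 (0.0771) did. Without the RelB-DBDB control library, Tbc1d2 (0.0539), Pou4f1 (0.0596) and Lyl1 (0.0877) did.

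Lists at 3 h showed the same inflammatory programme. Of the 23 inflammatory genes, 19 rose and 20 adjusted over the list alone, with a median log2 change of 2.82, smaller with a pseudocount of 5 (adjusted p = 1.51e-29, or 0.0527 with an estimated correlation). NF-κB regulators had 14 higher, among them Nfkbiz, Tnfaip2 (2.67), Zc3h12a (2.26), Tnfaip3 (2.01) and Nfkbia (1.51), and 1 lower, Map3k14, with 17 higher and 1 lower adjusted over the list alone (adjusted p = 2.4e-19, or 0.0527 with an estimated correlation). Dendritic cell maturation genes had 14 higher, led by Marcksl1 (3.54), Cd70 (3.30), Cd40 and Icosl (2.55), and 16 adjusted over the list alone (adjusted p = 2.51e-18, or 0.154 with an estimated correlation). Chemokines had 12 higher, with Ccl3 at 4.84 and Cxcl1 at 4.67, and 13 adjusted over the list alone (adjusted p = 4.29e-17, or 0.0527 with an estimated correlation). The Toll-like receptor pathway had 6 higher, among them Ikbke (2.44), Map3k8 (1.43), Irf4 (1.33) and Irf8 (1.03), and 8 adjusted over the list alone (adjusted p = 3.77e-06, or 0.141 with an estimated correlation). Antiviral interferon-stimulated genes (46 tested, 0 called by limma, 0 adjusted over the list alone) and guanylate-binding and immunity-related GTPases (13 tested, 0 called, 0 adjusted over the list alone) also passed upward (adjusted p = 2.95e-05 and 0.000154, or 0.928 for both with an estimated correlation). Both list calls ended without the RelB-DBDB control library (adjusted p = 0.959 and 0.0784), where the interferon-stimulated median turned from 0.732 to -0.171. By fry neither passed (0.813 and 0.557).

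At 8 h the largest increase was that of Marco. Genes induced by IL-4, with which the cells were cultured, were lower as a list (camera adjusted p = 0.0005, or 0.445 and no call with an estimated correlation). Marco, which encodes a scavenger receptor, rose 286-fold on the CPM + 1 scale, and the chemokine genes Cxcl3, Cxcl5, Cxcl1 and Cxcl2, the acute-phase gene Saa3, Lcn2 and the cytokine genes Il12b, Il1b, Il1a, Tnf and Il6 were high. Clec10a and Mrc1, lectin receptors induced by IL-4, fell with Alox15 and Arg1. The water-channel gene Aqp3 fell to near 0. Limma called 2654 genes, 801 higher and 1853 lower, all 2654 with the same sign in both genotypes. Of these, 484 higher and 1007 lower genes changed at least 2-fold. With median-ratio factors the split was 1247 higher and 1091 lower of 2338 genes, and with TMM factors 1211 higher and 1130 lower of 2341. Marco (chromosome 1, 120474538 to 120505024) went from 0.19 to 393 CPM in RelB-DBDB and from 0.0835 to 266 CPM in IFNAR;RelB-DBDB, a log2 change of 8.16 ± 0.255 (SE, adjusted p = 2.55e-05). Il12b reached 1045 and 1124 CPM (log2 6.51, adjusted p = 0.00014). Cxcl3 changed by 6.42, Il1b by 6.40, Il1a by 6.09, Ptgs2 by 5.96, Cxcl2 by 5.82 and Saa3 by 5.65. Aqp3 (chromosome 4, 41092722 to 41098183) went from 25.8 to 0.537 CPM in RelB-DBDB and from 20.0 CPM to 0 reads in IFNAR;RelB-DBDB, a log2 change of -4.26 ± 0.203 (adjusted p = 0.00014). Clec10a (chromosome 11, 70156197 to 70170834) went from 93.4 to 5.05 CPM and from 72.8 to 5.12 CPM (log2 -3.78 ± 0.171, adjusted p = 0.000129). Emp1 (-3.61), Matk (-3.58) and Ltb4r1 (-3.57) followed. Tnf stood at 5.09, Il6 at 4.73, Nfkbia at 1.23 and Ifnb1 at 1.44 (adjusted p = 0.00697), all called. Actb at 0.72 (adjusted p = 0.0213) and Gapdh at -0.87 (adjusted p = 0.0262) were called as well. Isg15, a ubiquitin-like antiviral gene, stood at 3.21 (adjusted p = 0.0462). Cxcl10 (2.72, adjusted p = 0.0803), Irf7 (1.84, adjusted p = 0.344) and Relb (0.20, adjusted p = 0.59) had no call. Neither had Tlr9 (-0.18) or Ifnar1 (-0.18), both above 0 with either other scaling.

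The RelB-DBDB 8 h library was the deepest and held 6.26% mitochondrial reads, against 1.74% to 2.41% in the others. The 8 h count was 336 without the RelB-DBDB control, 622 without the IFNAR;RelB-DBDB control, 1646 without either 1 h library, 1293 without the RelB-DBDB 3 h and 1287 without the IFNAR;RelB-DBDB 3 h library, and 7056 without the IFNAR;RelB-DBDB 8 h library. The Actb call ended in 6 of the 8 such fits (adjusted p 0.000572 to 0.27), that of Isg15 in 5 (0.000377 to 0.322, log2 1.58 without the RelB-DBDB 8 h library), that of Gapdh in 4 (2.91e-05 to 0.261) and that of Ifnb1 in 2, without the RelB-DBDB control (0.0647) or the IFNAR;RelB-DBDB control (0.0767). Ltb4r1 missed the threshold without the RelB-DBDB control (adjusted p = 0.0539). Isg15 also missed it with median-ratio (adjusted p = 0.0509) and TMM factors (0.0512), with no filter (0.102), with the filter of 50 reads (0.0518), with a pseudocount of 5 (0.0527) and without the genotype term (0.126). With no filter Actb (0.239) and Gapdh (0.0685) missed it, and without the genotype term Actb (0.132). Against a fold of 1.5 Isg15 (0.184), Ifnb1 (0.0694), Actb (0.956) and Gapdh (0.632) did. Relb stood at -0.29 (adjusted p = 0.031) without the IFNAR;RelB-DBDB 8 h library and at 0.68 (adjusted p = 0.00156) without the RelB-DBDB 8 h library. Tlr9 stood at -0.66 (adjusted p = 0.00436) without the RelB-DBDB 8 h library. Cxcl10 stood at 4.58 (adjusted p = 0.000162) and Irf7 at 4.54 (adjusted p = 0.000871) without the IFNAR;RelB-DBDB 8 h library, and at 0.85 (adjusted p = 0.245) and -0.86 (adjusted p = 0.395) without the RelB-DBDB 8 h library.

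**Figure D1:**
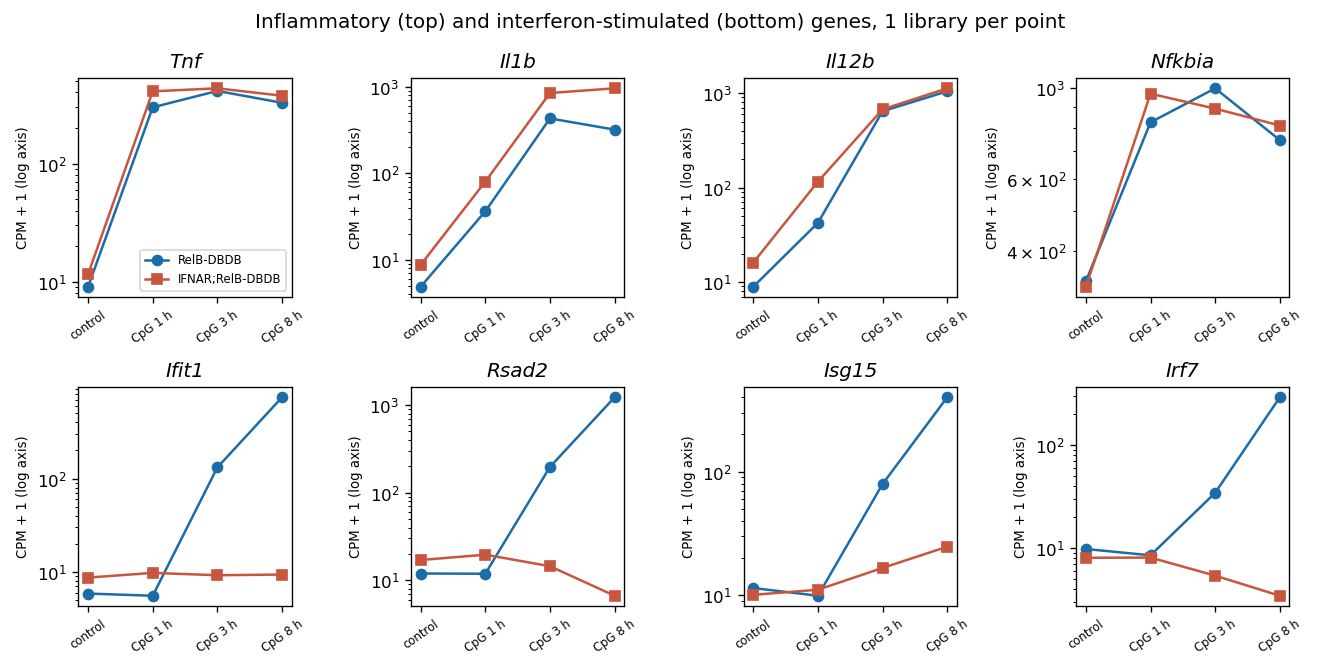
CPM + 1 on a log axis against condition (control, 1, 3 and 8 h of CpG) for 4 inflammatory genes (top) and 4 interferon-stimulated genes (bottom), with blue circles for RelB-DBDB, red squares for IFNAR;RelB-DBDB and 1 library per point. Tnf, Il1b, Il12b and Nfkbia rose in both genotypes, while Ifit1 reached 740 CPM in RelB-DBDB and 8.35 CPM in IFNAR;RelB-DBDB at 8 h.

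By list, inflammatory genes stayed high at 8 h, with 19 of 23 higher, 21 adjusted over the list alone and a median of 2.72 (adjusted p = 6.06e-24, or 0.0841 with an estimated correlation). Chemokines had 13 higher and 1 lower, 14 and 2 adjusted over the list alone (adjusted p = 1.95e-13, or 0.0841 with an estimated correlation). NF-κB regulators had 12 higher, 15 higher and 1 lower adjusted over the list alone (adjusted p = 3.35e-13, or 0.0841 with an estimated correlation). Maturation genes had 15 higher, led by Marcksl1 (3.25), Cd40 (2.93), Il15ra (2.18) and Fscn1 (2.10), and 18 adjusted over the list alone (adjusted p = 4.79e-15, or 0.198 with an estimated correlation). The Toll-like receptor pathway had 6 higher, led by Irak3 (2.49), and 6 adjusted over the list alone (adjusted p = 0.000232, or 0.198 with an estimated correlation). IL-4-responsive genes moved down, with 9 of 16 lower (Clec10a, Mrc1, Alox15, Arg1, Mgl2, Flt1, Retnla, Chil3 and Ccl24), 10 lower and 1 higher adjusted over the list alone, and a median of -1.07, or -0.84 relative to all genes (adjusted p = 0.0005, or 0.445 with an estimated correlation). Mrc1 changed by -2.70, Alox15 by -2.52 and Arg1 by -2.31, the last from 2675 to 435 CPM and from 1607 to 402 CPM. Sterol synthesis genes had 7 lower, among them Dhcr7 (-2.25), Sqle (-1.23) and Insig1 (-1.20), and 1 higher, with 12 lower and 1 higher adjusted over the list alone and a median of -0.66, or -0.43 relative to all genes (adjusted p = 0.00832, or 0.736 with an estimated correlation). That median was -0.262 without the RelB-DBDB 8 h library (adjusted p = 0.037) and -1.06 without the IFNAR;RelB-DBDB 8 h library. Oxidative phosphorylation genes had 7 of 20 lower, led by Cox5a (-1.22), 14 adjusted over the list alone, and a median of -0.59, or -0.36 relative to all genes (adjusted p = 0.0179, or 0.726 with an estimated correlation). Here the median was -0.283 without the RelB-DBDB 8 h library and -0.949 without the IFNAR;RelB-DBDB 8 h library. Glycolysis genes had 11 of 19 lower, led by Eno1 (-1.99), Aldoc (-1.77) and Tpi1 (-1.55), and 3 higher, Hk2, Slc2a6 and Slc2a1, which code for the first step and for glucose transport. Adjusted over the list alone they were 14 lower and 3 higher, with a median of -0.86, or -0.63 relative to all genes (adjusted p = 0.0369, or 0.641 with an estimated correlation). MHC class II genes had 5 of 11 lower, H2-Ob, H2-DMb2, H2-DMa, H2-DMb1 and H2-Oa, with 6 adjusted over the list alone and a median of -0.61, or -0.38 relative to all genes (adjusted p = 0.0369, or 0.641 with an estimated correlation). The MHC class II median was -0.405 without the RelB-DBDB control library. The glycolysis and MHC class II calls ended without either 3 h library (adjusted p = 0.063 without that of RelB-DBDB and 0.0631 without that of IFNAR;RelB-DBDB, for both lists).

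The interferon-stimulated list also passed upward at 8 h, with 5 higher (Ifi205, Isg15, Slfn5, Ms4a4c and Ly6c2), 2 adjusted over the list alone (adjusted p = 8.82e-13, or 0.641 with an estimated correlation). Its median of 1.86 was 0.196 without the RelB-DBDB 8 h library (adjusted p = 0.0216) and 3.52 without the IFNAR;RelB-DBDB 8 h library. The GTPases had Gbp3 (2.01) and Gbp2 (1.73) higher and 0 adjusted over the list alone (adjusted p = 4.83e-05, or 0.641 with an estimated correlation), a call that ended without the RelB-DBDB 8 h library (adjusted p = 0.098). Mitochondrially encoded and nuclear-retained RNAs (adjusted p = 0.00116, or 0.641 with an estimated correlation) and MHC class I genes (0.0369, or 0.445) moved up with 0 members called, and without the RelB-DBDB 8 h library their adjusted p was 0.223 and 0.64. In that fit the mitochondrial median fell from 1.03 to 0.181, and that of MHC class I turned from 0.0957 to -0.00922. Without the RelB-DBDB control library the MHC class I list lost its call (adjusted p = 0.152), as it did with no filter (0.0518). By fry the calls of interferon-stimulated genes, GTPases (adjusted p = 0.352 for both), mitochondrially encoded RNAs (0.35), MHC class I (0.417), MHC class II (0.0659), sterol synthesis and oxidative phosphorylation genes (0.117 for both) ended at 8 h. With the filter of 50 reads those of MHC class II (0.0518) and glycolysis genes (0.0535) ended, and without the genotype term that of MHC class II (0.108). Other lists did not pass by camera at 8 h but held called genes, and by fry some lists outside the camera calls passed. Anti-inflammatory regulators split into 4 higher, with Socs3 at 4.06 and Il1rn at 3.49, and 6 lower, with Il1r2 at -2.25, while 8 and 7 passed adjusted over the list alone. Immediate-early genes had 2 higher and 5 lower, 4 and 5 adjusted over the list alone, with Fosb at -2.69 and Klf2 at -2.49. Stress-response genes had 1 higher, Slc7a11 (1.02), and 3 lower, Asns (-1.53), Trib3 and Vegfa, with 1 and 4 adjusted over the list alone. Macrophage markers had 3 higher, Emr1 (2.09), Ly6c2 and C5ar1, and 4 lower, among them Mrc1, Ccr2 and Itgam. Neutrophil markers had Lcn2 (3.06) higher and Cxcr2, Ltf, S100a9 and Ngp lower.

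Between the genotypes, averaged over the 4 conditions, IFNAR;RelB-DBDB libraries held more RNA of T and NK cell markers and of cell cycle genes, list calls that ended with an estimated correlation (adjusted p = 0.248 and 0.47). Gzmc, Nkg7, Cd3d, Cd8a, Cd8b1, Cxcr6 and Il2rb, genes of cytotoxic lymphocytes, were higher, and so were the proliferation genes Ccna2, Top2a, Rrm2 and Kif11. RelB-DBDB libraries held more of Gpnmb, Mrc1 and Mmp8, of the protease inhibitor gene Spint1 and of the cytochrome P450 gene Cyp1b1. Limma called 769 of 12297 genes, 565 higher and 204 lower in IFNAR;RelB-DBDB, all 769 with the same sign in the 4 conditions, and 295 and 90 of them by at least 2-fold. Here too the shared sign follows largely from the model. With median-ratio factors 453 were higher and 326 lower of 779, and with TMM factors 454 higher and 322 lower of 776. Gzmc (chromosome 14, 56231441 to 56234656), which lies in a cluster of similar granzyme genes, stood at 6.09, 4.06, 5.81 and 4.73 CPM in RelB-DBDB (control, 1, 3 and 8 h) and at 36.4, 38.0, 37.7 and 52.0 CPM in IFNAR;RelB-DBDB. Its log2 difference was 2.77. Nkg7 (2.41, adjusted p = 0.00324), Cd3d (2.39), Cd8b1 (2.22) and Cd8a (2.19, adjusted p = 0.00144) were higher, as was Il2rb (2.39), at 19.5, 17.2, 14.3 and 4.62 CPM against 80.6, 79.5, 66.8 and 53.3 CPM. Eif3j2 had the largest positive difference (2.98 ± 0.203, SE, adjusted p = 0.00139), at 0 reads in RelB-DBDB control and 1 h, where its near copy Eif3j1 makes its reads uncertain. Slc15a2 (2.67), a peptide transporter gene on chromosome 16 (36750177 to 36784962), had 0 reads in RelB-DBDB control, 1 h and 3 h. It stood at 4.68, 6.20, 7.10 and 4.04 CPM in IFNAR;RelB-DBDB. Cxcr6 (2.63), Gbp5 (2.59) and Podnl1 (2.47) completed the largest increases. Cyp1b1 (chromosome 17, 79701537 to 79715061) had the largest negative difference, -3.84 ± 0.239 (adjusted p = 0.00139), at 15.3, 12.5, 13.3 and 46.1 CPM against 0.334, 0.255, 0.182 and 0.808 CPM. Spint1 (-3.18), Mmp8 (-2.94), Gpnmb (-2.62), Dio2 (-2.40), Rbp4 (-2.30), Ifi27l2a (-2.25), Cxcl3 (-2.34) and the antiviral genes Oas1g (-2.75) and Oas1a (-2.40) followed, the last pair being similar copies whose reads are uncertain. Gpnmb stood at 641, 728, 774 and 1627 CPM against 141, 132, 146 and 147 CPM.

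Among cytokine and receptor genes, Il1b was higher in IFNAR;RelB-DBDB by 1.13 ± 0.138 (SE, adjusted p = 0.00539). Tnf (0.27), Il12b (0.62), Ifnb1 (0.20) and Actb (0.25) had no call. Neither had Il6 (0.10), Cxcl10 (0.04), Nfkbia (0.04), Tlr9 (0.09) or Gapdh (0.04), each below 0 with either other scaling. Isg15 (-1.57) and Irf7 (-2.36, adjusted p = 0.208 for both) were not called either. With 1 library left out Isg15 lay between -2.15 and -0.757 and Irf7 between -3.12 and -1.01. In these fits Il6 lay between -0.205 and 0.349 and Cxcl10 between -0.485 and 0.974. Without the RelB-DBDB or the IFNAR;RelB-DBDB 8 h library, Tlr9 (0.33, adjusted p = 0.0175 or 0.0172), Il12b (0.79, adjusted p = 0.0372 or 0.0407), Tnf (0.29, adjusted p = 0.043 or 0.0459) and Actb (0.26, adjusted p = 0.0328 or 0.0315) passed. The genotype count was 252, 309 or 125 without the RelB-DBDB control, 1 h or 3 h library and 250, 309 or 124 without that of IFNAR;RelB-DBDB. It was 2040 without the RelB-DBDB and 2011 without the IFNAR;RelB-DBDB 8 h library. Without the RelB-DBDB or the IFNAR;RelB-DBDB 3 h library, Il1b (adjusted p = 0.0615 or 0.0619), Gbp5 (0.0762 or 0.0771), Oas1a (0.056 or 0.0557), Oas1g (0.08 for both) and Dio2 (0.0932 or 0.0943) missed the threshold with the same sign. With no filter Ifnar1 (0.0682) and Dio2 (0.0533) missed it, and against a fold of 1.5 Ifnar1 (1), Il1b (0.155) and Dio2 (0.0929). Without the condition block Ifnar1 (0.183), Il1b (0.859), Dio2 (0.06) and Cxcl3 (0.703) did.

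**Figure D2:**
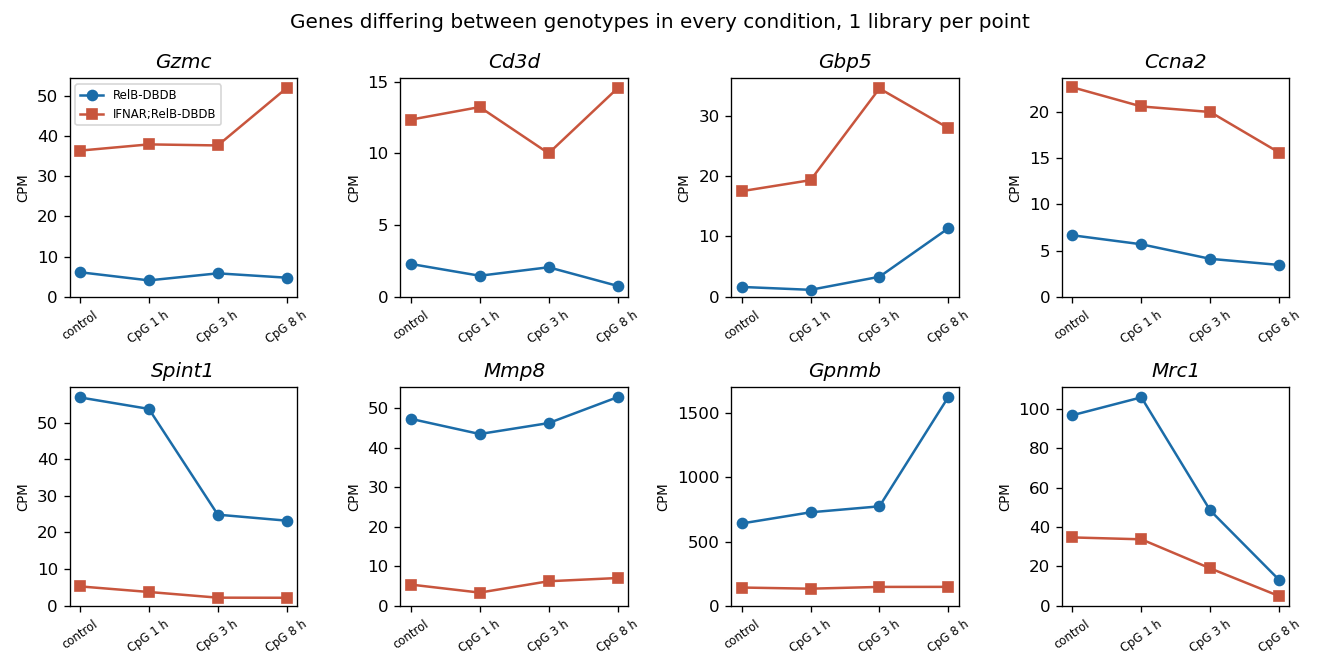
CPM on a linear axis from 0 in each of the 8 libraries for 4 genes higher in IFNAR;RelB-DBDB (Gzmc, Cd3d, Gbp5 and Ccna2) and 4 higher in RelB-DBDB (Spint1, Mmp8, Gpnmb and Mrc1), with 1 library per point. Gzmc lay between 36.4 and 52.0 CPM in IFNAR;RelB-DBDB and between 4.06 and 6.09 CPM in RelB-DBDB.

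Of 10 tested T and NK cell markers 9 were higher in IFNAR;RelB-DBDB (Nkg7, Il2rb, Cd3d, Cd8a, Lck, Trac, Cd3e, Gzmb and Cd3g), 9 adjusted over the list alone, with a median of 2.00, or 1.88 relative to all genes (camera adjusted p = 6.81e-12, or 0.248 with an estimated correlation). Of 30 cell cycle genes 26 were higher, 29 adjusted over the list alone, with a median of 1.18, or 1.06 relative to all genes (adjusted p = 7.67e-20, or 0.47 with an estimated correlation). Rrm2 (1.98), Kif11 (1.84), Ccna2 (1.82) and Top2a (1.79) led them. Of 8 mast cell and basophil markers 6 were higher, led by Mcpt8 (2.06) and Cpa3 (1.46), and 7 adjusted over the list alone (adjusted p = 0.000351, or 0.47 with an estimated correlation). Of 5 eosinophil markers Prg2 (1.80), Ccr3 (1.09) and Epx (1.02) were higher, 3 adjusted over the list alone (adjusted p = 0.00314, or 0.47 with an estimated correlation). Of 13 GTPases, which act against intracellular pathogens, Gbp5, Gbp2 (1.49) and Gbp8 (1.04) were higher, 5 adjusted over the list alone (adjusted p = 0.00209, or 0.735 with an estimated correlation). MHC class II genes had 3 higher, Ciita (1.08), H2-DMa (0.59) and H2-Ab1 (0.48), with 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.0129, or 0.696 with an estimated correlation). That call ended without either 3 h library (adjusted p = 0.0585 or 0.0583). Interferon-stimulated genes moved down, with a median of -1.29, or -1.40 relative to all genes, and 2 of 46 lower (Oas1a and Oas1g) and 2 higher, the same counts adjusted over the list alone (adjusted p = 6.81e-12, or 0.696 with an estimated correlation). This median was -0.389 without either 8 h library and -1.84 without either 1 h library, so it came mostly from the later conditions. Macrophage markers passed downward with Mertk (-2.11) and Mrc1 (-1.41) lower and Ccr2 (1.14) and Ly6c2 (0.97) higher, 2 higher and 3 lower adjusted over the list alone (adjusted p = 0.00264, or 0.47 with an estimated correlation). Chemokines passed downward with Cxcl9 (1.92) and Ccl4 (0.79) higher and Cxcl3 and Cxcl2 (-1.21) lower, 3 and 5 adjusted over the list alone (adjusted p = 0.0159, or 0.47 with an estimated correlation), but not without the RelB-DBDB or IFNAR;RelB-DBDB 8 h library (adjusted p = 0.0678 or 0.067). By fry the calls of interferon-stimulated genes (0.588), GTPases (0.285), chemokines (0.267) and MHC class II genes (0.0986) ended, and without the condition block those of chemokines (0.156) and MHC class II genes (0.0653).

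Inflammatory genes did not pass as a list between genotypes (median 0.114), with Csf2 (1.46) and Il1b higher and Nos2 (-0.92), Csf1 (-0.77) and Inhba lower. NF-κB regulators had only Nfkbid (0.85) higher, at a list median of 0.188, and 0 adjusted over the list alone. IL-4-responsive genes had 5 higher, led by Retnla (1.25), and 1 lower, and MHC class I genes had 5 higher, among them Psme2 (0.56) and Tap1 (0.53), and 9 adjusted over the list alone. Dendritic cell markers had H2-Ab1 higher, neutrophil markers Mpo (0.93) and Ctsg higher and Mmp8 lower, and B cell markers Ighm (1.34) higher. Stress-response genes had Sdf2l1 higher and Vegfa and Slc7a11 lower, maturation genes had Icosl and Adcy6 higher, immediate-early genes had Dusp2 and Btg2 higher and Fosl1 lower, the Toll-like receptor pathway had Irf1 (0.77) higher and Tlr7 (-1.52) lower, and anti-inflammatory regulators had Cish and Socs1 (0.93) higher. Plasmacytoid dendritic cell markers had none called. Stromal (4 tested), sex-linked (4), erythroid (1) and interferon genes (1, Ifnb1) were too few to test as lists. Among stromal markers Col1a2 (1.62) and Col1a1 (1.26) were higher. The Y-linked gene Ddx3y lay between 88.6 and 129 CPM and Xist between 0.167 and 0.912 CPM in the 8 libraries.

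How the genotypes differed over time was asked next, since secreted interferon can act only after it is made. Antiviral interferon-stimulated genes rose after CpG in RelB-DBDB, while in IFNAR;RelB-DBDB the list did not rise as a whole and single genes moved both ways. Ifit1, Ifit2, Rsad2, Cmpk2, Irf7 and Isg15, whose products block viral RNA and replication or carry the interferon signal onward, were higher in RelB-DBDB by 3 h and more so at 8 h. In IFNAR;RelB-DBDB Cmpk2 went from 13.5 CPM in control cells to 1.08 CPM at 8 h, and Rsad2 and Irf7 fell as well. Ifit1 (chromosome 19, 34640871 to 34650009) stood at 4.85, 4.55, 131 and 740 CPM in RelB-DBDB (control, 1, 3 and 8 h) and at 7.68, 8.74, 8.19 and 8.35 CPM in IFNAR;RelB-DBDB. Rsad2 (chromosome 12, 26442746 to 26456452) stood at 10.9, 10.9, 196 and 1226 CPM against 16.03, 18.6, 13.5 and 5.66 CPM, and Irf7 at 8.75, 7.47, 33.3 and 290.0 CPM against 7.01, 7.05, 4.37 and 2.43 CPM. Isg15 rose from 10.5 to 397 CPM in RelB-DBDB and stood at 9.10 and 23.7 CPM in IFNAR;RelB-DBDB at control and 8 h. The list's median change from control to 8 h was 3.70 in RelB-DBDB, with 46 of 46 genes positive, and -0.02 in IFNAR;RelB-DBDB. From control to 3 h it was 1.38 and -0.10. The median genotype difference was 0.11 in control libraries, 0.26 at 1 h, -1.44 at 3 h and -4.02 at 8 h. At 3 h and at 8 h it lay below all 10000 random lists matched on expression. Inflammatory genes rose in both genotypes, by a median of 2.51 and 2.88 at 3 h and of 2.62 and 2.58 at 8 h (RelB-DBDB and IFNAR;RelB-DBDB). Ifnb1 had 0, 0, 8 and 50 reads in RelB-DBDB and 0, 2, 6 and 8 reads in IFNAR;RelB-DBDB, which is 1.34 and 2.16 CPM at 8 h.

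**Figure D3:**
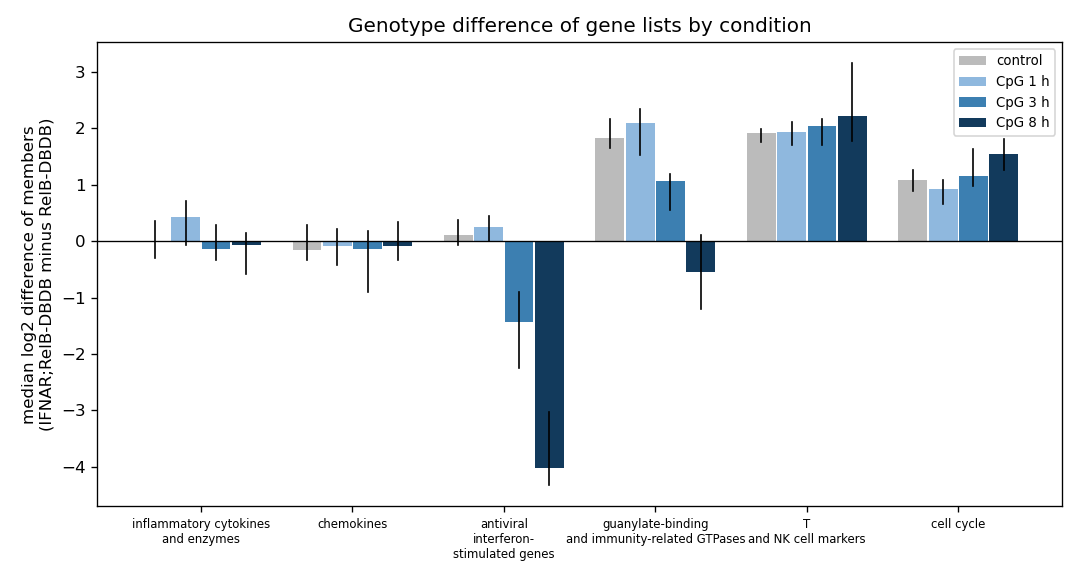
Median log2 difference (IFNAR;RelB-DBDB minus RelB-DBDB, CPM + 1) of 6 gene lists in control libraries and at 1, 3 and 8 h of CpG, with lines for bootstrap 95% intervals over list members. Antiviral interferon-stimulated genes went from 0.11 to -4.02 while T and NK cell markers lay between 1.92 and 2.22.

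The test of the late phase set the genotype difference at 3 and 8 h against that in control and at 1 h. Limma called 0 genes, with 874 at an unadjusted p under 0.05 and a smallest adjusted p of 0.201, and limma-voom also called 0. The largest negative values with no call were those of Cmpk2 (-6.92), Ifit2 (-6.43), Rsad2 (-6.26), Ifit1 (-5.76 ± 0.726, SE, adjusted p = 0.31) and Irf7 (-4.36). Isg15 stood at -3.12, Cxcl10 at -3.03, Il6 at -1.18, Il12b at -1.07, Tnf at -0.26 and Il1b at 0.29. The Il12b value came from higher early levels in IFNAR;RelB-DBDB. At 1 h Il12b stood at 41.2 CPM in RelB-DBDB against 114.5 CPM, and at 8 h at 1045 against 1124 CPM. Il6 was higher in IFNAR;RelB-DBDB early (50.0 against 102.1 CPM at 1 h) and lower late (392.5 against 250.3 CPM at 8 h). The largest positive values were those of Yam1 (3.69), Lars2 (3.14), Mir6236 (2.55), Gdf15 (1.66) and Kbtbd11 (1.52). Cmpk2, Ifit2, Rsad2, Ifit1, Irf7, Isg15, Cxcl10 and Lars2 were called in all 8 fits with 1 library left out, with adjusted p of 9.35e-23 to 1.59e-13 for Cmpk2, 1.77e-19 to 9.07e-13 for Ifit1 and 6.92e-14 to 0.00124 for Cxcl10. Those fits have 1 residual degree of freedom and 24.1 to 1190 prior degrees of freedom taken over all genes, against 2 and 4.67 with all libraries, so these p-values rest on a spread shared by all genes and were not taken as calls. Yam1 and Mir6236 passed in 6 of them, Il6, Il12b, Gdf15 and Kbtbd11 in 4 and Il1b in 2. The count depended on single libraries, since it was 69, 71, 5641 or 701 without the RelB-DBDB control, 1 h, 3 h or 8 h library and 70, 72, 5632 or 688 without that of IFNAR;RelB-DBDB. With 8 h alone as the late phase, where the contrast rests on a single pair of libraries, it was 3582.

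As lists, 10 passed in the late phase by camera, none of them with an estimated correlation (adjusted p = 0.646 for all). Interferon-stimulated genes had a median of -2.50 (adjusted p = 2.97e-48) with 42 of 46 lower adjusted over the list alone, and the GTPases one of -1.80 (adjusted p = 1.07e-14) with 9 of 13. Mitochondrially encoded and nuclear-retained RNAs (-0.98), inflammatory genes (-0.19, 4 adjusted over the list alone), the Toll-like receptor pathway (-0.15), MHC class I genes (-0.19) and plasmacytoid dendritic cell markers (-0.48, 5 members) also moved down. Down means that the genotype difference fell, which higher early values in IFNAR;RelB-DBDB can bring about as well as lower late ones. Cell cycle (0.39), oxidative phosphorylation (0.37) and MHC class II genes (0.34) moved up. The median of interferon-stimulated genes moved toward 0 by over 1.5 times without either 8 h library, and away from 0 by less than that without either 3 h library. Without either 8 h library that of the GTPases was -1.16, that of mitochondrially encoded RNAs -0.315, that of cell cycle genes 0.226, that of oxidative phosphorylation 0.0855, that of plasmacytoid dendritic cell markers -0.229 and that of MHC class I genes -0.0333. Without either 3 h library it was -1.63 for mitochondrially encoded RNAs, 0.674 for oxidative phosphorylation and -0.305 for MHC class I genes, and without either control -0.253 for the Toll-like receptor pathway. Interferon-stimulated genes, GTPases, mitochondrially encoded RNAs and the Toll-like receptor pathway passed in all 8 fits with 1 library left out, and plasmacytoid dendritic cell markers in none (adjusted p 0.0651 to 0.328). Without the RelB-DBDB or the IFNAR;RelB-DBDB 1 h library 5 lists passed, and inflammatory genes (adjusted p = 0.326 or 0.343), oxidative phosphorylation (0.0877 or 0.0874), cell cycle (0.13 or 0.134), MHC class II (0.201 or 0.203) and class I genes (0.054 or 0.0536) did not. Without the RelB-DBDB or the IFNAR;RelB-DBDB control the MHC class II (0.134 or 0.133) and class I calls (0.105 or 0.104) ended, without the 3 h library of either those of MHC class II (0.0679 or 0.0699) and cell cycle (0.204 or 0.224), and without the 8 h library of either that of MHC class I (0.548 or 0.562). With median-ratio or TMM factors MHC class II genes (0.0599 or 0.059) and plasmacytoid dendritic cell markers (0.0771 or 0.0752) missed the threshold. MHC class II genes also missed it with the filter of 50 reads (0.0549) and a pseudocount of 5 (0.0553), and MHC class I genes with no filter (0.0731). By fry only plasmacytoid dendritic cell markers passed. With 8 h alone as the late phase the Toll-like receptor pathway (0.0563), MHC class II (0.258), cell cycle (0.382) and plasmacytoid dendritic cell lists (0.0749) missed it. With stimulated against control as the contrast the lists of the Toll-like receptor pathway (0.271), MHC class II, oxidative phosphorylation (0.378 for both), plasmacytoid dendritic cell (0.117), inflammatory (0.642, with a median of 0.0316) and cell cycle genes did.

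Each condition was then compared between single libraries, which gives ratios with counting intervals and no test. In control libraries, before CpG, Gbp5 was 10.8-fold higher in IFNAR;RelB-DBDB (95% interval 6.61 to 19.0), the immunity-related GTPase gene Iigp1 6.38-fold (5.49 to 7.46) and the T cell kinase gene Lck 7.23-fold (4.94 to 10.9), and Eif3j2 and Slc15a2 had 92 and 56 reads against 0. The GTPase list stood at a median difference of 1.83 in control libraries, 2.09 at 1 h, 1.06 at 3 h and -0.55 at 8 h. Cyp1b1 was 45.9-fold lower (17.6 to 170), Abi3bp 17.1-fold, Spint1 10.8-fold, Cxcl3 9.68-fold and Mmp8 8.86-fold. At 1 h Gbp5 was 17-fold, Iigp1 10.2-fold and Gzmc 9.35-fold higher, and Cxcl9, an interferon-γ-induced chemokine gene, had 103 reads against 1, a ratio of 53.9 (9.46 to 2150). Cyp1b1 (49.1-fold), Spint1 (14.4-fold), Mmp8 (13.1-fold), Yam1 (9.28-fold) and Mfap1a (8.20-fold) were lower at 1 h. At 3 h Eif3j2 was 28.2-fold, Themis 11-fold, Ifng, which encodes interferon γ, 10.6-fold (5 to 25.8), Gbp5 10.5-fold and Gzmc 6.48-fold higher. Mx2 (44.4-fold, 17.2 to 164), Cmpk2 (17.8-fold), Ifit1 (15.9-fold), Rsad2 (14.6-fold) and Ifit2 (14.3-fold) were lower at 3 h. At 8 h Cd3d was 19.3-fold, Cxcr6 17.5-fold, Nkg7 15.3-fold, Il2rb 11.5-fold and Gzmc 11-fold higher. At the same time Cmpk2 had 4 reads against 11170 (278-fold lower, 109 to 1020), Rsad2 21 against 45615 (217-fold lower, 142 to 350), Ifit3 3 against 6058 (201-fold lower, 68.9 to 977), Ifit2 was 131-fold lower (92.7 to 191) and Irf7 had 9 reads against 10795 (120-fold lower, 63.0 to 262).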

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

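Tests chosen only after the result was seen were the comparison of T and NK with neutrophil markers, the median-ratio scaling and the 3 h value of the interferon-stimulated genes, the correlations of Yam1, and the positive control of the sequence search.

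The RelB-DBDB 8 h library lay far from the other 7 in depth (37.22 M reads against at most 11.98 M reads), in the share of mitochondrial reads (6.26% against at most 2.41%) and in the share of reads in its 20 highest genes (15.7% against at most 12.8%). Its gap to the next library was 0.753, 0.852 and 0.562 of the whole range. These were 3 of 7 measures tested over the 8 libraries, all in the same library, and chance alone gives such a gap in about 1 of 20 groups tested. It also lay apart on the first principal component, at 75.2 against -36.7 to 25.1 for the others.

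The genotype difference changed between the early and the late conditions for 10 lists by the interaction test with a preset correlation, and for none of them with an estimated correlation (adjusted p = 0.646 for all). The median late-phase change was -2.50 for antiviral interferon-stimulated genes, -1.80 for guanylate-binding and immunity-related GTPases, -0.983 for mitochondrially encoded and nuclear-retained RNAs and -0.480 for plasmacytoid dendritic cell markers. It was -0.187 for inflammatory genes, -0.154 for the endosomal Toll-like receptor pathway and -0.186 for MHC class I genes. It was 0.394 for cell cycle, 0.365 for oxidative phosphorylation and 0.338 for MHC class II genes. The mitochondrial and oxidative phosphorylation values go with the RelB-DBDB 8 h library, where mitochondrial reads were highest: their genotype differences were -1.25 and 0.685 at 8 h against 0.0712 and 0.116 at 3 h. No single gene was called by limma or limma-voom in this test (874 at an unadjusted p under 0.05). The 4 conditions allow only 3 partitions into pairs, too few for a share under 0.05. All 3 gave 0 calls, so the highest other was 0, and at an unadjusted p under 0.05 the others gave 118 and 82 genes against 874.

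Interferon-stimulated genes were lower late in IFNAR;RelB-DBDB, by a median of -1.44 at 3 h and -4.02 at 8 h, a late-phase list call lost with an estimated correlation. Scaling of the libraries is argued against, since with median-ratio factors the 8 h median was -4.37 (bootstrap interval -4.67 to -3.37). With every library thinned to the smallest the median was -4.04 (-4.34 to -3.08). Random thinning leaves the expected CPM unchanged, so this test could hardly have moved the median and does not decide on unequal depth. The unusual RelB-DBDB 8 h library is not the whole cause, since the 3 h median of -1.44 came from other libraries and lay below the lowest random list (-0.164). The loss of IFNAR named by the design would predict this pattern and may account for it, but each genotype is 1 series of libraries, so any other difference between the cultures or animals stays open.

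T and NK cell genes were higher in IFNAR;RelB-DBDB, a list call lost with an estimated correlation (adjusted p = 0.248), with 9 of 10 markers called singly. The genotype count behind this was 769, and of 32 splits of the 8 libraries that could be fitted 1, the real one, reached it, with 9 as the highest other. Only 8 of these splits part the libraries of all 4 conditions as the genotype does, too few for a share under 0.05, and their highest other was 0. More T and NK cells in these cultures would raise genes outside the marker set, and of 32 further genes of these cells 27 were tested and 27 were positive, with a median of 1.36 (1.13 to 1.72) and 20 called (23 adjusted over the list alone). A lower share of dendritic cells as the only cause would raise all other cell types alike, and the T and NK median lay 1.81 (1.24 to 2.24) above that of neutrophil markers. That set also holds genes that moved with CpG, such as Lcn2 (33.7 CPM in RelB-DBDB control and 268 CPM at 8 h). No other cell type was compared in this test, so it does not decide the point. A lower share of dendritic cells may take part, since mast cell and basophil markers (median 0.938, 6 of 8 higher), eosinophil markers (1.02, 3 of 5 higher), Ighm (1.34) and Col1a2 (1.62) were higher as well. The dendritic cell markers themselves gave no sign of a loss. Their called gene, H2-Ab1, was higher in IFNAR;RelB-DBDB (1957 CPM against 1469 CPM in RelB-DBDB, control libraries). The fixed markers most particular to NK cells, Ncr1 and Klrb1c, did not pass the filter, so this set does not tell NK from T cells. More T cells, with or without NK cells, may explain the T and NK cell genes, with levels such as 53.3 CPM of Il2rb and 52.0 CPM of Gzmc at 8 h, and the labels name no sort that would remove them. Whether this follows from the genotype or from another difference between the cultures or animals stays open.

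Yam1, Lars2 and Mir6236 differed widely between libraries. Yam1 held 1.74% of the reads in the RelB-DBDB 1 h library, 0.188% in the IFNAR;RelB-DBDB 1 h library and 0.0661% in the RelB-DBDB 8 h library. A common source would make them rise and fall together. Over the 8 libraries Yam1 and Lars2 had a Spearman rho of 0.833 (exact permutation p = 0.0154, adjusted 0.0231). Their Pearson r was 0.982 (exact permutation p = 0.000298, adjusted 0.000744), or 0.949 without the 2 farthest libraries. Mir6236 gave rho 0.833 and r 0.978 (0.88 without the 2 farthest). Gm26917, the last of the 3 relations computed, gave r 0.647 (exact permutation p = 0.0848), which became -0.468 without the 2 farthest. Yam1, Lars2 and Mir6236 were named for the largest positive late-phase values in these same libraries, a choice that favours such correlations. The permutation p-values do not allow for that choice, so a common source stays open. Reads from ribosomal RNA cannot be told apart from other sources. Lars2 and Mir6236 shared 0 words of 25 bases with the ribosomal-RNA-like transcripts Gm26917, Gm42418 and AY036118, a result set beforehand as evidence against it, but Gm26917 also shared 0 with its own kind while the other 2 shared 899, so the search misses such sequences and that bound was wrong. No biological explanation was tested.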

How the results depend on the processing

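The added settings, chosen only after the data were seen, were totals without mitochondrial and Yam1 reads, the gene test settings applied to the lists and a pseudocount of 5 for the interferon-stimulated median. Without mitochondrial and Yam1 reads the counts were 9, 1018, 2808, 794 and 0 (1 h, 3 h, 8 h, genotype and late), all within 1.5 times the main 8, 924, 2654, 769 and 0. Median-ratio and TMM factors, the filter of 50 reads and both pseudocounts also stayed within 1.5 times, with the splits given in the results.

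At 1 h the count was 4 without the genotype term. At 3 h it was 478 with no filter, 148 against a fold of 1.5 and 334 without the genotype term. At 8 h it was 1629 with no filter, 4316 by limma-voom, 479 against a fold of 1.5 and 1229 without the genotype term. For the genotype it was 413 with no filter, 104 against a fold of 1.5, 286 without the condition block, and 251, 293, 124 and 2043 without the control, 1 h, 3 h and 8 h pair. The late phase as 8 h alone gave 3582 against 0. A test against a fold of 1.5 asks for more by construction; the other causes were not tested.

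Leaving out 1 library in turn gave 5 to 35 genes at 1 h (without the IFNAR;RelB-DBDB 1 h and the RelB-DBDB 8 h library), 12 to 4313 at 3 h (without the RelB-DBDB 3 h and 8 h library) and 336 to 7056 at 8 h (without the RelB-DBDB control and the IFNAR;RelB-DBDB 8 h library). It gave 124 to 2040 for the genotype (without the IFNAR;RelB-DBDB 3 h and the RelB-DBDB 8 h library) and 69 to 5641 for the late phase (without the RelB-DBDB control and 3 h library). Such fits have fewer residual degrees of freedom (2 against 3, or 1 against 2 in the late phase), and the cause was not tested.

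With an estimated correlation 0 lists passed at 1 h, 3 h, 8 h, between genotypes and in the late phase, against 7, 7, 14, 9 and 10. With so few residual degrees of freedom that setting could hardly pass any list, so it does not decide between the 2 results. By fry 3 passed at 1 h, 9 at 8 h, 5 between genotypes and 1 in the late phase. With 1 library left out 7 to 12 passed at 1 h and 5 to 12 in the late phase, and 6 with stimulated against control as the late phase. There the median of the inflammatory list was 0.0316 (adjusted p = 0.642) against -0.187, a reversed sign. Relb at 8 h went from 0.20 to -0.29 (adjusted p = 0.031) without the IFNAR;RelB-DBDB 8 h library and to 0.68 (adjusted p = 0.00156) without the RelB-DBDB 8 h library, over a range of adjusted p from 0.00156 to 0.979. The cause was not tested.

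The 8 h median of interferon-stimulated genes was -4.37 with median-ratio and -4.36 with TMM factors against -4.02, and -3.15 with a pseudocount of 5. Among named genes the direction and side of the threshold were the same in 331 of the values recomputed at 1 h, 396 at 3 h, 431 at 8 h and 724 between genotypes. The call was lost in 22, 40, 31 and 33 and gained in 6, 13, 4 and 12, and 1 value at 8 h, that of Relb, was reversed. In the late phase 337 were the same and 118 gained a call, most of them in the fits with 1 residual degree of freedom. The DESeq2 alternatives were not run. Depth limits genes below 0.808 CPM, which is 3 reads of the shallowest library.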

Other observations

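The test of Ifng reads was chosen only after the result was seen, and the list of further interferon-γ-inducible genes was written before its values were examined.

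Guanylate-binding and immunity-related GTPases were higher in the control IFNAR;RelB-DBDB library (median 1.83). There the median of antiviral interferon-stimulated genes differed little (0.114), while single members went both ways. In control libraries Oas1a stood at 22.9 CPM in RelB-DBDB and 5.51 CPM in IFNAR;RelB-DBDB, and Ly6a at 17.8 and 77.8 CPM. A candidate explanation for the GTPases is interferon γ made in the IFNAR;RelB-DBDB cultures, since it acts through another receptor than IFNAR. Of 13 further interferon-γ-inducible genes 12 were tested and 12 were positive in the control libraries, with a median of 1.15 (bootstrap interval 0.581 to 1.64), above all random lists matched on expression. Genes that move together for any reason could lie outside such lists, so that place does not point to interferon γ in particular. Ifng itself had 92 reads against 32 in the control libraries, a ratio of 2.52 (1.67 to 3.90). It stood at 7.68, 9.42, 9.65 and 11.3 CPM in IFNAR;RelB-DBDB and at 3.04, 2.27, 0.912 and 0.940 CPM in RelB-DBDB (control, 1, 3 and 8 h). T and NK cells, whose genes were also higher, are a possible source. These are single libraries, so the difference between them has no replicate check.

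Across 12297 genes the response of the genotypes correlated with a Pearson r of 0.384 at 1 h, 0.78 at 3 h and 0.652 at 8 h, where genes are not independent replicates. Ifna2, Ifna4, Ifna5 and Ifnab had 0 reads in all 8 libraries.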
